A study of Mus musculus with 2 samples.

How the data were processed

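RNA was sequenced from TEa T cells sorted from spleen in 2 libraries, 1 per group. Per the labels' protocols, RNA was extracted with Trizol from flash-frozen sorted cells and made into low-input total RNA libraries with a Takara kit. Low-input kits amplify the cDNA by PCR, and no molecular identifiers are recorded in the table, so copies of a molecule can be counted more than once. The authors deposited 1 table of whole-number read counts per gene, not normalized, with 1 column per library. Per the file headers, the table also gives each gene's symbol, chromosome, strand, start, end, length and type. Per the submitters' processing notes, reads were handled with STAR 2.6 on genome build mm10. The counting program, its strand setting, its treatment of reads shared between genes and the annotation release are not given in the sources used here. Coordinates below are those of the deposited table.

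The 2 columns carry the titles of the 2 samples and were mapped by those names. The table held 35275 genes, of which 17536 had 0 reads in both libraries, and every row has a gene ID and name. Total counts were 7844445 in the effector library and 8508129 in the exhausted library. With 1 library per group no spread between animals can be estimated. The difference therefore has no replicate check and no p-value was computed for any gene.

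The design was fixed before the data were examined. Genes with at least 50 reads over both libraries counted as measured, which left 9999. Counts were divided by effective library sizes from edgeR 4.0.16 (trimmed mean of M-values, TMM), in R 4.3.3, and the ratio of exhausted to effector was taken. A 95% interval of each ratio came from the exact Clopper-Pearson interval of a gene's reads in the exhausted library among its reads in both (scipy 1.17.1). Intervals cover counting error only and take each read as independent, so amplified copies of a molecule would make them too narrow. A gene counted as higher or lower in the exhausted library when the ratio was at least 2-fold and the interval excluded equality. A library with 0 reads of a gene was set to a floor of 3 reads. For measured genes a fold against it understates the counted difference, but the lower counting limit can be smaller still. Where the other library has only 1 or 2 reads, the ratio points the wrong way, which can affect list medians without a read minimum. Folds are on the scale of scaled counts, with no pseudocount.

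On simulated data with counting noise only, run on the 9999 genes of this comparison, the rule found 100 of 100 genes changed 3-fold and 100 of 100 changed 8-fold. It passed 5 of 9799 unchanged genes (0.05%). With an assumed biological coefficient of variation of 0.1, 0.2 or 0.4 between libraries and no gene changed, it passed 17, 255 and 2389 of the 9999 genes. The real coefficient of variation is unknown here.

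A total of 35 gene lists were fixed in advance, 10 of them markers of other cell types. They held 582 distinct genes of the table, 50 of which sit in more than 1 list, so the lists are not independent. For 7 entries the symbol was matched through the Ensembl ID, and 3 entries had no match. For each list the median log2 ratio of its measured members was set against 10000 random lists of the same size drawn from measured genes in the same of 10 expression bins. That comparison describes these libraries, is not a test across animals, and was made for the 27 lists with at least 3 measured members. It put 10 lists above and 9 below the central 95% of random lists. If list members varied independently, 1.35 would be expected outside on both sides together. Random lists hold unrelated genes, so lists of genes that vary together can fall outside more often, even without a group difference.

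Genes named in the text followed a rule set in advance. It took the 12 protein-coding genes with the largest ratios and the 12 with the smallest, with at least 200 reads in the library where they were higher, leaving out symbols of the form Gm or Rik with a number and olfactory and vomeronasal receptors. It added up to 4 members per list with the largest absolute log2 ratio, and 21 genes of T cell identity and function. Genes named beyond it, such as Actb, receptor constant segments, overlapping neighbours and members that complete a count, were chosen after their values were seen. Some genes that the rule names are not reported here. T cell receptor segments were compared as the share of Trbv reads in Trbv19 (V beta 6) and of Trav reads in Trav14 members (V alpha 2), with exact Clopper-Pearson intervals.

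Alternatives changed the scaling (DESeq2 1.42.0 size factors, total counts, upper quartile), the read minimum (1 or 500), the genes counted, the depth (thinning the deeper library), the size rule (interval wholly beyond 2-fold, or at least 4-fold), the floor (a prior count of 2) and the summary of a list (summed counts). Exon overlap between genes was looked up in GENCODE M21, and GC content was taken from the longest M21 transcript of each gene. No column of another sample was in the table.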

Results

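The series compared TEa cells that had met abundant antigen with TEa cells that had met a moderate amount, and asked how their transcriptomes differ. TEa cells are T cell receptor transgenic CD4 T cells of C57BL/6 background that recognise a peptide of the BALB/c class II molecule chain I-E alpha. In the effector group they were transferred into wild-type C57BL/6 mice given a BALB/c skin graft. In the exhausted group they were transferred into CB6F1 mice, hybrids of BALB/c and C57BL/6 whose own cells inherit the antigen. Recipient strain and skin graft thus differ between the groups together with the amount of antigen, and the design cannot tell these apart. Group names are the submitters' titles. Each group held 1 library of sorted spleen TEa cells, with 7844445 counted reads for effector and 8508129 for exhausted cells. At least 1 read was counted for 16051 genes in the effector library and for 15864 in the exhausted library. Because there was 1 library per group, every fold below compares these 2 libraries, its interval covers counting error only, and no value has a replicate check.

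Both libraries had the receptor of TEa cells as their main T cell receptor. Trbv19, the V beta 6 segment of the transgenic receptor, took 96.0% of Trbv reads in the effector library (16882 of 17580, exact 95% interval 95.7 to 96.3%). It took 96.5% in the exhausted library (13968 of 14481, 96.1 to 96.8%). Members of Trav14, the V alpha 2 family, took 94.8% of Trav reads in the effector library (94.56 to 95.03%) and 92.5% in the exhausted library (92.1 to 92.9%). Nearly all of these lay in Trav14d-3-dv8, with 31697 and 13494 reads, and near-identical copies of this segment can share reads. Cd4 had 9272 and 15463 reads, which was 1.54-fold more in the exhausted library (1.502 to 1.582), and Cd8a had 0 reads in both, which allows up to 3 reads in each library. The antigen's own locus, annotated on the C57BL/6 genome as H2-Ea-ps, had 0 and 2 reads, both under the floor of 3.

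The 2 libraries shared most of their expression levels and differed strongly in a minority of genes. Of 9999 measured genes, 665 were at least 2-fold higher and 707 at least 2-fold lower in the exhausted library, 13.7% of the total, and 8627 were neither. A difference of at least 8-fold was seen in 111 genes upwards and 113 downwards. The median absolute log2 ratio over all measured genes was 0.33 and their median was -0.002. Genes at the top included the cytokine genes Il4 (2 against 600 reads, 277-fold, 76.4 to 2295) and Il21 (16 against 1501, 86.7-fold, 53.2 to 152), the macrophage growth factor gene Csf1 (21 against 3581, 158-fold, 103 to 255) and the inhibitory receptor gene Lag3 (3 against 361, 111-fold, 37.8 to 542). The others of the top 12 were Kirrel3, Fam84a, Chst3, Rap1gap, Thbs1, Vdr, Nrgn and Gstm1. Among them Thbs1, which encodes the matrix protein thrombospondin, had 0 against 651 reads. Against the floor of 3 reads it was 200.6-fold higher (lower counting limit 162.7). The vitamin D receptor gene Vdr had 8 against 948 reads. Gstm1 belongs to a family of similar genes and its count is uncertain for that reason.

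At the other end, the monocarboxylate transporter family gene Slc16a5 had 456 against 1 read (493-fold lower, 88.1 to 19525). Trat1, which encodes an adaptor bound to the T cell receptor, had 716 against 3 reads (258-fold lower, 88.0 to 1255). The others of the 12 were Ly6c1, Cd22, Capn3, Cd7, Hid1, Tgfbr3, Ctla2a, Sorl1, Pdlim4 and Rras2. Tgfbr3, the gene of the TGF-beta coreceptor betaglycan, was 60.5-fold lower (38.5 to 101), and Sorl1, the gene of a sorting receptor, had 2593 against 85 reads and was 33.0-fold lower (26.6 to 41.5). Ly6c1 and Ctla2a have near-identical neighbours that can share their reads. Capn3 shares exon sequence with Ganc on its own strand, and Slc16a5 overlaps Gm11695 on the other strand, where the strand setting of the counting is not known.

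**Figure D1:**
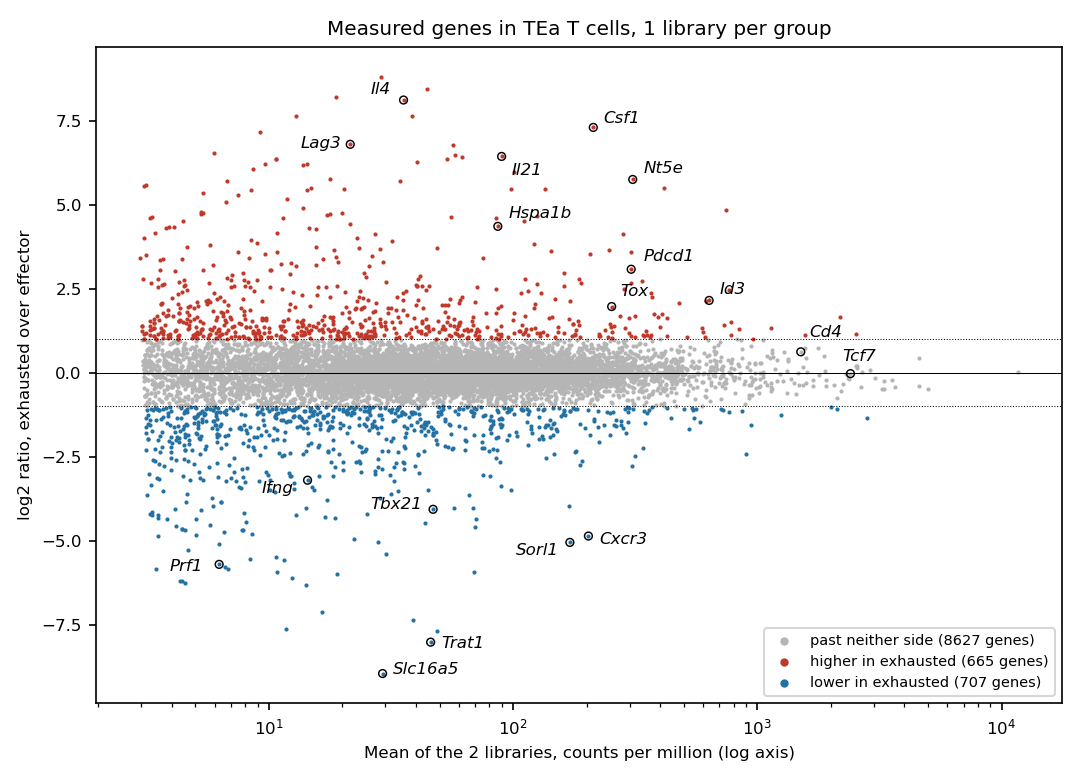
Log2 ratio of exhausted to effector against the mean scaled CPM (log axis) of the 9999 measured genes, 1 point per gene, 1 library per group. Of these genes, 665 lie in red (higher in the exhausted library), 707 in blue (lower) and 8627 in grey, with dotted lines at a 2-fold difference and named genes circled.

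Genes of the inhibitory receptor list were split in direction. Such receptors restrain activated T cells, but the list also holds genes of other kinds, such as Nt5e (an ectoenzyme) and Cd200 (a ligand). Of 14 measured members 5 were higher, 4 lower and 5 neither. Pdcd1, which encodes PD-1 (ENSMUSG00000026285, mm10 chromosome 1, 94038305 to 94052553), was 8.47-fold higher in the exhausted library (503 against 4607 reads, 7.72 to 9.30). Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705) was 111-fold higher. Nt5e, which encodes the ectoenzyme CD73 (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092), was 53.9-fold higher (88 against 5132 reads, 43.7 to 67.3). The other 2 higher members, named after their values were seen, were Cd200 (6.34-fold) and Btla (2.57-fold). Lair1 was 8.46-fold lower (5.41 to 13.8) and Tigit 3.11-fold lower (2.04 to 4.84). Cd200r1 and Cd101, also named afterwards, were 2.46-fold and 2.25-fold lower. Ctla4 did not reach 2-fold (464 against 762 reads, 1.52-fold, 1.35 to 1.71), and Havcr2, which encodes TIM-3, had 24 against 0 reads and was not measured by the rule. The list's median log2 ratio of 0.61 exceeded that of 9994 of 10000 matched random lists.

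Transcription factor genes associated with exhaustion were mostly higher. Of 15 measured, 8 were higher, 3 lower and 4 neither, with a median log2 ratio of 1.29 that exceeded all 10000 random lists. Their mean log2 ratio was only 0.38. Tox, a regulator of exhausted T cells (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557), was 3.92-fold higher (805 against 3415 reads, 3.63 to 4.24). Maf was 4.74-fold higher (4.01 to 5.62) and Irf4 3.16-fold higher (2.70 to 3.71). Batf was equal within 2-fold (668 against 700 reads). Prdm1, which encodes BLIMP-1, was 20.3-fold lower (75 against 4 reads, 7.6 to 76.4), Eomes 5.73-fold lower (53 against 10, 2.89 to 12.6), and Tox2, named after its value was seen, 3.34-fold lower. Genes associated with anergy, the lasting unresponsiveness of T cells that met antigen without full costimulation, had 6 of 15 higher, 1 lower and 8 neither, and a median of 0.61, above 9997 of 10000 random lists. Besides Nt5e these included Folr4, which encodes folate receptor 4 (5.55-fold higher, 5.28 to 5.83), Nrp1, which encodes neuropilin 1 (6.22-fold, 5.47 to 7.10), and Rnf128, which encodes the ubiquitin ligase GRAIL (17.8-fold, 9.15 to 39.5). The lower member was Ndrg1, named afterwards.

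Effector cytokine and cytotoxic genes were largely lower in the exhausted library, with 8 of 13 measured members lower, 4 higher and 1 neither. Prf1, which encodes perforin (ENSMUSG00000037202, chromosome 10, 61297836 to 61304263), had 96 against 2 reads (51.9-fold lower, 13.99 to 435). Gzmb, which encodes granzyme B, was 27.9-fold lower (129 against 5 reads, 11.7 to 87.4) and Fasl 19.5-fold lower (253 against 14, 11.4 to 36.3). Ifng was 9.15-fold lower (203 against 24, 5.98 to 14.6) and Il2 6.08-fold lower (45 against 8, 2.84 to 14.9). The 4 higher members were Il21 and, named after their values were seen, Gzmc, Tnfsf10 and Cst7. The median log2 ratio was -1.77, below all 10000 random lists. It depended on genes of low count, since it was 0.065 over members with at least 500 reads and the ratio of summed counts, to which Il21 adds 1501 reads, was 0.17 on the log2 scale.

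Th1 genes were lower, with 9 of 11 measured members lower, none higher and 2 neither, and a median log2 ratio of -1.80, below all 10000 random lists. Tbx21, which encodes the Th1 master regulator T-bet (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331), was 16.7-fold lower (694 against 45 reads, 12.3 to 23.1). Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269) was 28.9-fold lower (3076 against 115, 24.0 to 35.2). Il12rb2 was 25.5-fold lower, although its exons overlap Serbp1 on the other strand, and Il12rb1 was 2.41-fold lower. Ly6c2 was 11.4-fold lower (8.40 to 15.8). Cd44, an activation marker, was 2.96-fold lower (1628 against 595 reads, 2.69 to 3.26).

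**Figure D2:**
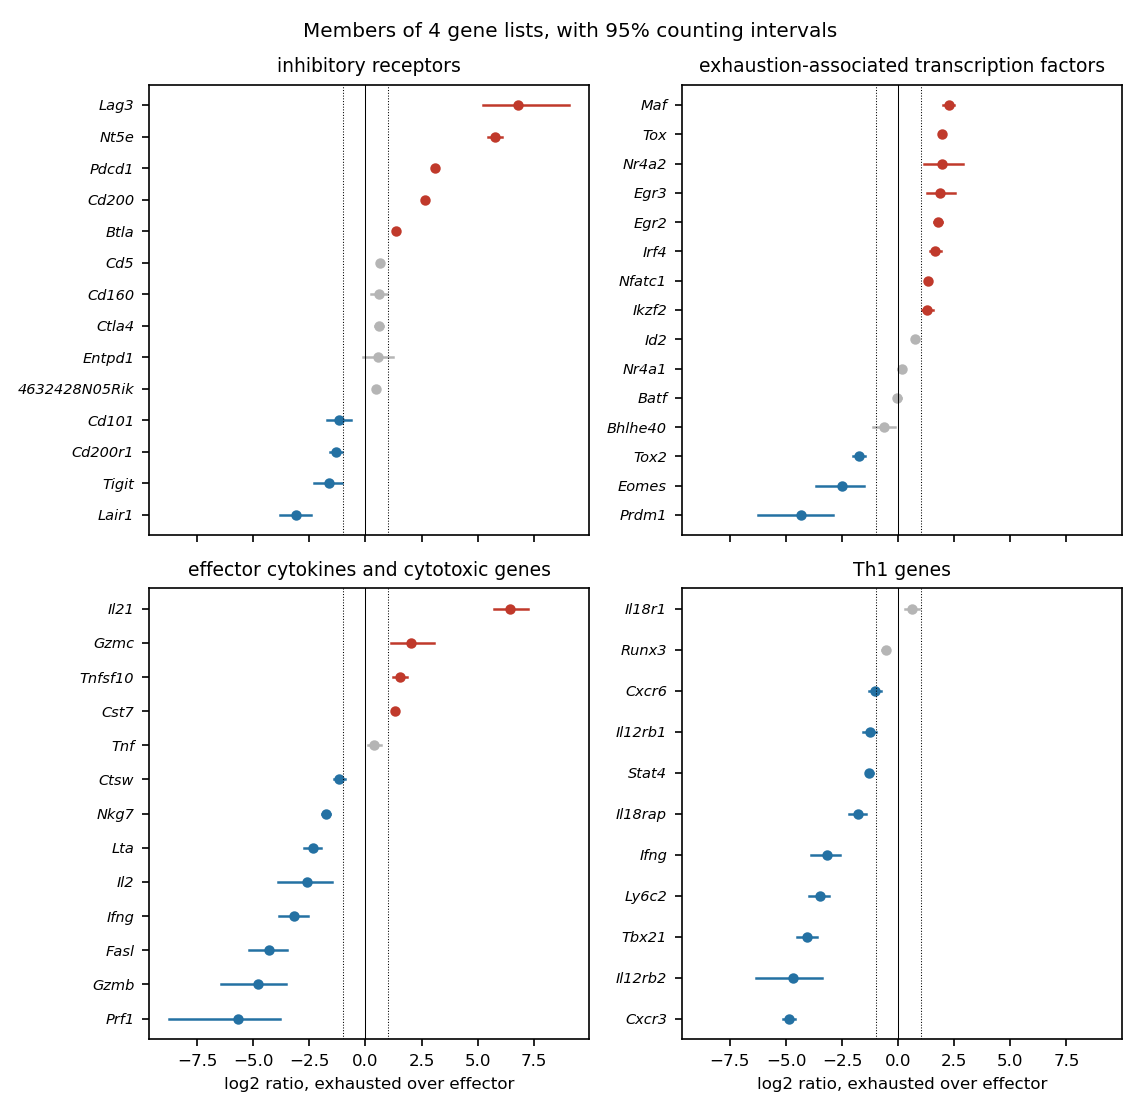
Log2 ratio of exhausted to effector for each measured member of 4 gene lists, 1 point per gene with its exact 95% counting interval, in red where higher, blue where lower and grey where neither. Pdcd1, Nt5e, Lag3 and Il21 stand on the right, and 9 of 11 Th1 genes stand to the left of the dotted line at 2-fold.

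Other helper programmes were mixed. Of 13 measured Tfh genes, which mark follicular helper cells, 6 were higher, 2 lower and 5 neither, and the median of 0.85 exceeded 9999 of 10000 random lists. Il21 (chromosome 3, 37222759 to 37232618), Sostdc1 (29.8-fold, 14.3 to 75.1), Pdcd1 and Tnfsf8 (6.62-fold, 6.11 to 7.18) were higher. Cxcr5, the follicle-homing receptor gene, was 11.2-fold lower (1413 against 137 reads, 9.36 to 13.4), with exon overlap to Bcl9l on the other strand. Il21 has an annotated antisense neighbour, Gm12534, with 0 and 127 reads. Of 5 measured Th2 genes, Il4 (chromosome 11, 53602982 to 53618669) and Nfil3 (16.1-fold, 10.4 to 26.3) were higher, and Ccr4 (3.99-fold, 2.79 to 5.85) and Il4ra (2.18-fold, 2.03 to 2.33) were lower. Their median of 0.73 exceeded 9919 of 10000 random lists. Of 3 measured Th17 genes Rora (2.12-fold) and Il1r1 (6.93-fold) were higher and Ahr was 3.95-fold lower. Their median of 1.08 exceeded 9726 of 10000 random lists, within the central 95%, and was -0.41 after the deeper library was thinned, when fewer members were measured. Of 12 Treg genes 4 were higher, 3 lower and 5 neither. Their median of 0.60 was above 9990 of 10000 random lists, but their mean was 0.03. The higher members included Nrp1, Folr4 and Tnfrsf9 (2.45-fold), whereas Foxp3, the lineage-defining factor gene, had 44 against 12 reads (3.97-fold lower, 2.06 to 8.25) and overlaps Ppp1r3f on the other strand. Il2ra was 20.6-fold lower (57 against 3 reads, 6.69 to 103) and Ikzf4 6.49-fold lower.

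Genes of naive and memory T cells were at similar levels in both libraries, with 14 of 19 neither, 4 higher and 1 lower. Their median was -0.02 and their mean 0.06. Tcf7 had 18980 against 20198 reads and Il7r 1391 against 1417, with log2 ratios of -0.02 and -0.09. Id3 was 4.45-fold higher (4.23 to 4.68), Slamf6 2.46-fold and Rgs10 2.08-fold higher, and Satb1 was 3.20-fold lower (3.05 to 3.36). Chemokine receptor and homing genes had 8 of 19 lower, 2 higher and 9 neither, with a median of -0.45, below 9997 of 10000 random lists. Besides Cxcr3 and Cxcr5 these included Ccr2 (34.3-fold lower, 11.4 to 169) and Ccr9 (14.4-fold lower, 6.70 to 36.7). Cytokine receptor genes had 6 of 21 lower, 2 higher and 13 neither, with a median of -0.45, below all 10000 random lists. They included Il12rb2, Il2ra and Il10rb (2.74-fold lower). Costimulatory genes had 4 of 14 higher, 1 lower and 9 neither, with a median of 0.57, above 9999 of 10000 random lists. The higher members were Tnfsf8, Tnfsf14 (4.45-fold, 3.59 to 5.56), Tnfsf11 (2.33-fold) and Tnfrsf9, and the lower one, named afterwards, was Cd226. Of 8 TGF-beta and regulatory cytokine genes 3 were higher and 5 neither. Lag3 is among them, Tgfb1 was 2.17-fold and Tgfb3 4.68-fold higher, and Smad7 was not past the rule (433 against 235 reads). The list's median of 0.23 exceeded 9100 random lists, within their central 95%, and was -0.35 over members with at least 500 reads.

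Genes of T cell receptor signalling had 5 of 22 lower, none higher and 17 neither, and their median of -0.07 lay within the central 95% of random lists. The lower members included Trat1, Grap2 (5.47-fold, 4.44 to 6.79), Cd6 (2.17-fold) and, named afterwards, Lat. Cd3e had 7624 against 11432 reads (1.39-fold). Of the receptor's constant segments, named after their values were seen, Trac was 2.11-fold lower (22526 against 11561 reads), whereas Trbc2 differed by less than 2-fold (29944 against 27705).

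Heat shock genes, which encode protein-folding chaperones, were higher together. Of 11 measured, 9 were higher, none lower and 2 neither, with a median log2 ratio of 1.33, above all 10000 random lists. Hspa1b was 20.5-fold higher (63 against 1397 reads, 15.9 to 26.8) and Hspa1a 19.8-fold higher, and these near-identical genes can share reads. Hsph1 was 5.15-fold (4.80 to 5.53) and Dnajb1 3.24-fold higher (3.03 to 3.46). Reads of mitochondrially encoded genes made up 0.404% of the effector library and 0.569% of the exhausted library (exact 95% intervals 0.4 to 0.409% and 0.564 to 0.574%). Counts were uneven among these genes, with 12098 effector reads of mt-Co1 and 232 of mt-Co3. How reads shared with similar sequences were counted is not known, so these shares cannot be read as RNA or cell quality. Of 11 mitochondrially encoded genes measured, 1 was past the rule, mt-Nd3 (2.01-fold), and mt-Cytb (1.55-fold) and mt-Co3 (1.74-fold) were not. Their median of 0.51 exceeded 9962 of 10000 random lists. Immediate early genes had 2 of 13 lower, Fos (2.91-fold, 2.64 to 3.20) and Klf6 (2.15-fold), none higher and 11 neither, among them Egr1 (1650 against 3134 reads) and Junb (3533 against 2107). Their median was 0.19, their mean -0.17, and their median without a read minimum -0.52.

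Type I interferon response genes had 6 of 27 lower, none higher and 21 neither, and a median of -0.64, below all 10000 random lists. Ifit2 was 3.10-fold lower (2.57 to 3.76), Usp18 2.52-fold, Ifit1 2.47-fold and Ifi27l2a 2.29-fold. Glycolysis genes had 4 of 19 lower, 1 higher and 14 neither, and their median of -0.15 lay within the central 95% of random lists. Aldoc (4.54-fold), the glucose transporter gene Slc2a3 (3.04-fold) and Pdk1 (2.57-fold) were lower, and the lactate transporter gene Slc16a3 was 4.79-fold higher (17 against 88 reads, 2.83 to 8.58). None of 46 nuclear-encoded oxidative phosphorylation genes passed the rule, although their median of -0.18 was below 9961 of 10000 random lists. Examples were Sdhb (1732 against 1209 reads), Ndufb10, Ndufa10 and Cox8a, of which Cox8a had the larger count in the exhausted library. None of 40 cell cycle genes passed it either. Their median of 0.20 exceeded 9874 of 10000 random lists, with Mcm5 at 890 against 1893 reads (1.97-fold, 1.81 to 2.13), Ccne2 at 1.99-fold, Mcm6 at 1.75-fold and Tk1 at 1.70-fold. Log2 ratios lay above 0 for 27 of the 40 genes and below 0 for 13. The latter included, named afterwards, Aurkb (1.55-fold lower) and Ccnb1 (1.51-fold lower). Ccne2 overlaps Ints8, Tk1 overlaps Afmid and, among the immediate early genes, Junb overlaps Prdx2, each on the other strand. None of 56 measured ribosomal protein genes passed it, with a median of 0.09, within the central 95%. Examples were Rpsa, Rplp1 and Rpl35. Of 22 apoptosis genes 2 were higher, 2 lower and 18 neither, with a median of 0.10 and a mean of -0.13. The proapoptotic genes Pmaip1 (5.58-fold, 3.70 to 8.73) and Bbc3 (3.43-fold, 2.63 to 4.54) were higher, and Fas (7.28-fold, 5.68 to 9.44) and Fasl were lower.

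**Figure D3:**
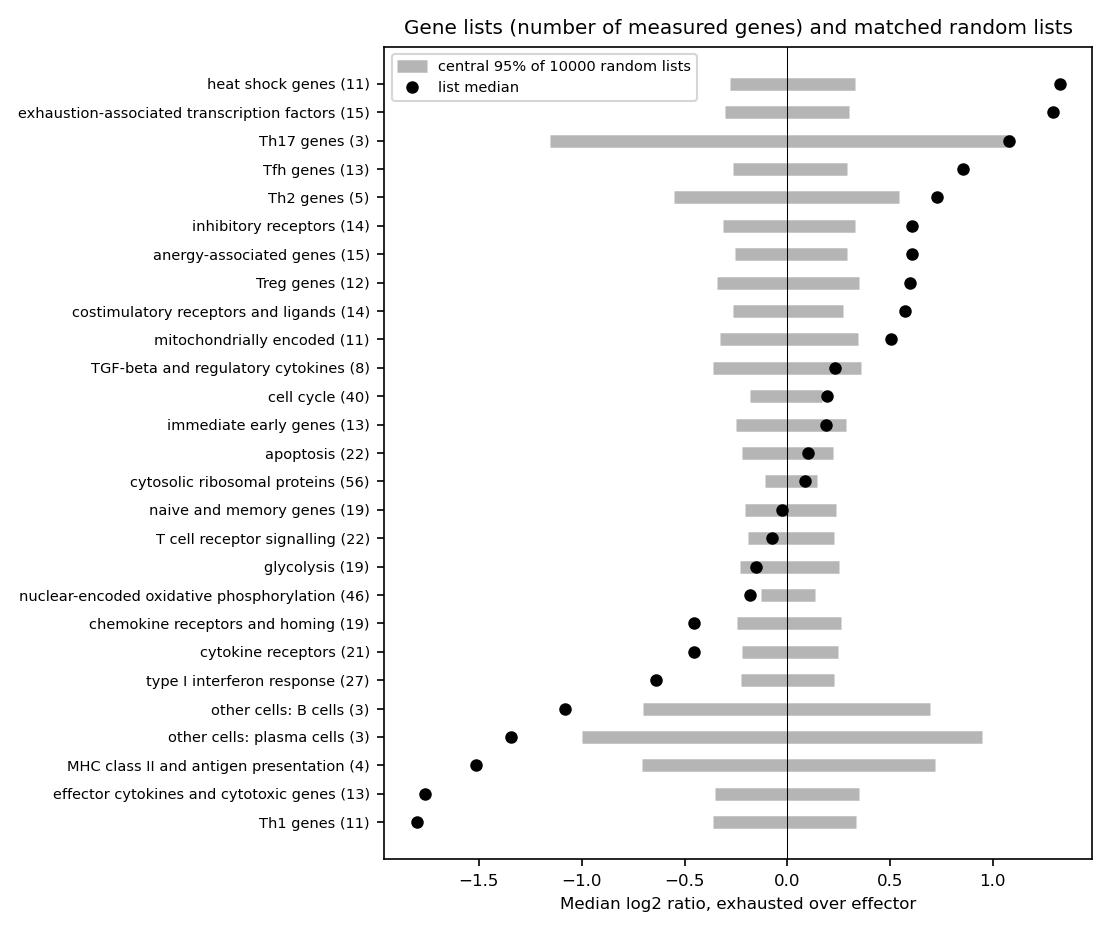
Median log2 ratio of exhausted to effector (black points) for the 27 gene lists with at least 3 measured genes (number in brackets), beside the central 95% of 10000 matched random lists (grey bars). The lists of heat shock genes (1.33) and exhaustion-associated transcription factors (1.29) lie farthest to the right, and those of Th1 genes (-1.80) and effector cytokine and cytotoxic genes (-1.77) farthest to the left.

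Most markers of other spleen cells were not measured. Of the 21 measured members of these and the class II lists, 11 were lower in the exhausted library, as most Th1 and effector genes were, 1 was higher and 9 were neither. Among B cell markers 3 of 14 were measured, and 2 of them, Cd22 (603 against 4 reads) and Ighm (7540 against 3851, 2.12-fold lower, 2.04 to 2.20), were lower, while Igkc (223 against 133) was neither. The list's median of -1.08 was below 9926 of 10000 random lists. Without a read minimum it was 0.47, the log2 ratio that the floor gives a gene with 2 against 0 reads. Its sign therefore cannot be read as a direction. Cd74, the gene of the class II invariant chain, had 64 against 53 reads. Of 3 measured plasma cell markers Slamf7 (16.1-fold, 9.41 to 30.1) and Igj (2.54-fold) were lower and Xbp1 (817 against 1673 reads) was neither, with a median of -1.35, below 9886 of 10000 random lists, that was 0.92 over members with at least 500 reads. Cd8b1 was 2.19-fold lower (164 against 81 reads). Of NK cell markers Klrb1c was 5.88-fold higher (36 against 229 reads, 4.13 to 8.61) and Eomes lower. Among macrophage markers Ly6c2, which T cells also express, was lower and Hmox1 (39 against 33) neither. The single measured neutrophil marker, Mpo, had 39 against 49 reads. Among dendritic cell markers Ccr9 was lower and Bst2 neither (305 against 204), and both are genes that T cells also express. Of erythroid markers Hba-a1 was 9.01-fold lower (50 against 6 reads) and Car2 neither (32 against 19). No platelet marker was measured, and of stromal and endothelial markers Pecam1 alone was measured (2093 against 3198 reads, 1.41-fold). Of 4 measured class II and antigen presentation genes Cd86 (278 against 15 reads, 20.05-fold, 11.9 to 36.3) and H2-Ob (6.27-fold, 4.67 to 8.55) were lower, and H2-DMa and Cd74 neither, with a median of -1.52, below 9977 of 10000 random lists. H2-DMa overlaps Brd2 on the other strand.

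Protein-coding genes took 97.3% of reads in the effector and 97.8% in the exhausted library. Ribosomal protein genes took 2.22% and 2.28%, the 10 most abundant genes 4.96% and 4.42%, and immunoglobulin and T cell receptor segments 1.59% and 0.970%. Actb was the most abundant gene in both, with 90571 and 99903 reads.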

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

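The alternatives were planned, and were run on the genes named beyond the rule after the data had been seen. The numbers of genes higher and lower in the exhausted library, 665 and 707, moved by over 1.5 times with the read minimum and the size rule. They were 1034 and 1104 without a read minimum, 244 and 264 with at least 500 reads, 408 and 453 with the interval wholly beyond 2-fold, and 220 and 238 at 4-fold. Under the 3 other scalings, the 2 other gene sets and thinning of the deeper library the numbers lay between 605 and 677 higher and between 662 and 709 lower, and under the scalings the median log2 ratio of all genes lay between -0.006 and 0.011. For 134 genes of the naming rule 1135 of 1135 alternative values lay inside the counting interval of the main value, and for 25 genes named beyond it 210 of 210 did. That outcome was nearly fixed in advance and is no measure of robustness. Other scalings, read minimums and gene sets keep a gene's counts and shift the log2 scaling by -0.013 to 0.004. The 2 lists written afterwards were not run under the alternatives. Of 333 alternative list medians 280 stayed inside their counting interval, 45 moved beyond it with the same sign and 8 changed sign. The inhibitory receptor median of 0.61 became 1.01 with at least 500 reads and 1.51 as a ratio of summed counts. The effector cytokine median of -1.77 became -1.47 without a read minimum and changed sign to 0.065 with at least 500 reads and 0.17 from summed counts. The others that changed sign were immediate early genes (-0.52) and B cell markers (0.47) without a read minimum, TGF-beta genes (-0.35) and plasma cell markers (0.92) with at least 500 reads, plasma cell markers from summed counts (0.56), and Th17 genes (-0.41) after thinning. The members tested differ under a read minimum, and for summed counts the abundant members weigh most. Medians without a read minimum can include genes with 1 or 2 reads against 0, whose ratio the floor turns the wrong way. The B cell median there has the value that the floor gives 2 against 0 reads, so its change of sign cannot be read as a direction. As shares of protein-coding reads, mitochondrial genes took 0.415% of the effector and 0.581% of the exhausted library, ribosomal protein genes 2.29% and 2.33%, and the 10 most abundant genes 4.93% and 4.47%. The receptor segment shares stayed inside their intervals. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. The table cannot show the spread between animals. With an assumed coefficient of variation of 0.4 and no change, 2389 genes would pass the rule.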

Other observations

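Genes of sterol synthesis and uptake were lower in the exhausted library. This list of 24 genes was written after 4 of them, with Sqle, Idi1 and Hsd17b7 included, had been seen among the genes with small ratios. Of the 24, 17 were lower, none higher and 7 neither, with a median log2 ratio of -1.64. Sqle, which encodes squalene epoxidase, had 1055 against 56 reads (20.4-fold lower), Hsd17b7 256 against 33 (8.39-fold) and Idi1 378 against 51 (8.02-fold). Hmgcs1 was 5.84-fold lower (1820 against 337 reads), Mvk 4.98-fold and Fdft1 4.69-fold, whereas Stard4 had 264 against 270. The hypothesis that the pathway as a whole, and not the 4 genes seen beforehand, was lower in these libraries was tested on the other 20 genes, with the prediction written before their values were seen. Of these 13 were lower and their median of -1.53 lay below that of 10000 of 10000 matched random lists. With 1 library per group, whether it follows the antigen, the recipient strain or the graft, or differs from mouse to mouse, was not tested.

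The tests on all Th1 and effector list genes, immediate early genes, receptor segments, NK cell genes and B cell genes below were chosen after the values had been seen. The lists of sterol and chaperone genes were also chosen after other values had been seen, with their tests set before those of the genes tested.

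The heat shock genes, with a median log2 ratio of 1.33, may reflect handling or the state of the cells. A trend over GC content or gene length is argued against, since the median of the 11 genes was 1.39 after both trends were removed. Handling stress that also induces immediate early genes cannot be told apart from a difference between the recipients, because those genes had a median of 0.19 with members on both sides and handling can differ between 2 libraries. Endoplasmic reticulum chaperone and unfolded protein response genes, in a list written after the heat shock values were seen and without Hspa5, had a median of 0.31, above that of 9934 of 10000 random lists, but 1 of 19 was past the rule upwards (Hyou1, 2.92-fold), 1 downwards (Edem1, 3.44-fold) and 17 neither. The difference between recipients stays open and untested.

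The 23 measured genes of the Th1 and effector lists had a median log2 ratio of -1.76 before and -1.72 after the GC and length trends were removed, which argues against these as the cause. The median of the 16 lower genes alone, -2.90 before and -2.76 after, decides nothing, because these genes were chosen for being lower. More T cells without the TEa receptor in the effector library would need a share of Trbv reads outside Trbv19 at least 2 times as high there, and the ratio was 1.12 (exact 95% interval 0.999 to 1.26). If the cells behind these reads alone expressed Cxcr3, they would hold 9906 CPM of it, near the 11579 CPM of Actb in the library, although a different state of such cells in the 2 libraries is not excluded for genes of low count. NK cell RNA as the source of Tbx21 is argued against by 5.91 reads of 5 NK cell genes per 100 Tbx21 reads in the effector library. Klrb1c gave 36 of these 41 reads, and the other 4 genes 5 reads there and 1 in the exhausted library. For cytotoxic genes of low count, such as Prf1 (96 effector reads) and Gzmb (129), the test cannot decide, because it was set against Tbx21 alone. A difference between the TEa cells of the 2 recipients stays open, as does one between individual mice, neither of them tested.

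Ighm, the immunoglobulin mu constant gene, had 7540 and 3851 reads in sorted T cells. B cell RNA would bring its other abundant transcripts, but 6 B cell genes, with Cd74, Cd79a and Cd79b included, together had 93 and 76 reads, which is 1.23 and 1.97 per 100 Ighm reads. With Cd22 (603 against 4 reads) and Igkc (223 against 133), the other measured B cell markers, the sums were 919 and 213 reads, or 12.2 and 5.53 per 100, so whether B cell RNA is excluded in the effector library depends on the genes chosen, and it stays open. Cd22 differed between the libraries far more than Cd74 (64 against 53), and why was not tested. Transcription of the locus in the T cells themselves is a candidate explanation that was not tested.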
